A study of Mus musculus with 16 samples.

How the data were processed

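RNA of 16 mouse sciatic nerve samples, 4 per genotype, had been sequenced after selection for polyadenylated RNA with reads of 150 bases. Per the submitters' processing notes, the software was CASAVA 1.9, STAR and DESeq2, with the GRCm38/mm10 genome. The program that counted reads and the gene annotation are not given in the sources used here. The deposited data were 6 tables, 3 of each kind, one for each pair of genotypes: wild type with Xbp1 SC-KO, wild type with S63del, and S63del with S63del/Xbp1 SC-KO.

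The authors' deposited TPM values (transcript abundance scaled to the same total in each library) cover 49315 genes. The comparison tables list 16211 genes for S63del and wild type, 16277 for Xbp1 SC-KO and wild type and 16136 for S63del/Xbp1 SC-KO and S63del. In these, the authors' deposited signal per library was a read count divided by a size factor set within the table. Multiplying by the factor gave whole reads for 100% of values within a tolerance of 0.01. Reads of the same library differed between tables for 0 of the genes that tables share. The log2 fold changes in those tables were made by the authors, per the file headers, with the sign of the second genotype over the first. The p-values and adjusted p-values there are also as deposited by the authors, and the headers do not name the test. DESeq2 1.42.0, run on the recovered reads, differed from the authors' log2 values by 0.001 or more for 0 genes and made the same calls (3775, 10 and 5042).

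Reads on listed genes ran from 15206278 to 20766411 per library. Between replicates of a genotype, read counts differed by 7.19 to 51.3 times the variance of counting alone (chi-square per degree of freedom), so no library was a copy of another of its genotype. Libraries of different genotypes were not compared in this way. Of the gene identifiers, 48970 were paired with symbols and 49056 with positions on GRCm38. No sample column was left unused. The labels give no batch and no sex.

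Values were computed as log2(TPM + 1). Each pair of genotypes was fitted on its own 8 libraries with limma 3.58.1 (trend, R 4.3.3), on genes at 1 TPM or more in at least 4 of them. The interaction was a contrast of a 4-group limma model on all 16 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. Tests are two-sided. All adjusted p-values without another source named come from limma or from the list tests run on its fits. The tests, filters, gene lists, named-gene rule and most alternatives were chosen before the data were examined.

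Genes are named by a rule with 3 parts. Xbp1 and Mpz are given in every comparison. For each pair, the 10 largest rises and 10 largest falls are named among called genes with a mean of at least 5 TPM, groups that do not overlap, and a symbol that is not a predicted-gene name. From each gene list, up to 4 members with the smallest adjusted p are named. For the interaction the second part takes 5 genes each way without the condition on overlap. Genes outside the rule are said to be so where they appear.

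The 25 gene lists cover ER chaperones and foldases, ER-associated degradation, ER translocation and ER-to-Golgi transport, PERK-ATF4-CHOP targets, amino acid synthesis with import and tRNA charging, IRE1-dependent decay substrates, myelin, cholesterol synthesis, fatty acid synthesis, immature and repair Schwann cells, Remak (non-myelinating) Schwann cells, mitosis, cytosolic heat shock, immediate early genes, mitochondrially encoded mRNAs, macrophages, lymphocytes with mast cells and neutrophils, chemokines with interferon response, fibroblasts and matrix, perineurial cells, endothelial cells, adipocytes, skeletal muscle, red blood cells and sex-linked transcripts. Sex-linked transcripts had too few tested members in S63del against wild type and in Xbp1 SC-KO against wild type, which left 24 lists there. Each list was tested against other genes with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. With the latter, the amino acid list in the interaction was the only call that held. The fry test, which asks whether a list moves 1 way and does not compare it with other genes, was an alternative. Members were counted over all genes tested and adjusted over the list alone. List means per library were also compared by exact permutation.

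Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling of TPM, the replicate number as a block, array weights, Xist as a covariate, a single fit of all 16 libraries, the authors' deposited calls, removal of genes within 20 Mb of Xbp1, and each library left out in turn. After the data were examined, edgeR 4.0.16 and DESeq2 on recovered reads and the removal of 3 muscle-rich libraries were added. TPM stayed the main scale, as planned, because the comparison tables omit genes with few reads. The limma, edgeR and camera tests were first run on simulated data with known changes, while DESeq2, fry and the permutation test were not.

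The authors' comparison tables were otherwise not used. Splicing of Xbp1 and the deleted part of the gene could not be examined, since the tables hold 1 value per gene. Reads give counting error only, and differences between animals enter through the replicates.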

Results

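Polyadenylated RNA of mouse sciatic nerve was sequenced in 16 libraries, 4 for each of 4 genotypes, at an age the labels give as P30, read here as postnatal day 30. The genotypes were wild type, Xbp1 SC-KO, S63del and S63del/Xbp1 SC-KO. In Xbp1 SC-KO a floxed Xbp1 gene was removed by Cre driven from the P0 promoter, which is active in Schwann cells. S63del is a mutant form of Mpz, the gene of the main protein of peripheral myelin, and S63del/Xbp1 SC-KO carried both. S63del is called an allele below, although the values here do not show whether it replaces an Mpz copy or is added to them. The sample descriptions place S63del on a different mouse strain from the floxed Xbp1 and Cre lines. Xbp1 encodes a transcription factor whose active, spliced form is made when the endoplasmic reticulum (ER) kinase IRE1 senses misfolded protein. The S63del mouse is a model of an inherited demyelinating neuropathy. Each library held between 15206278 and 20766411 reads on the genes listed in the comparison tables. The labels name no batch and no sex, and Xist stood above the Y-linked Ddx3y in 2 wild-type, 3 Xbp1 SC-KO, 3 S63del and 1 S63del/Xbp1 SC-KO libraries. Levels below are means ± SD in TPM (transcript abundance scaled to the same total in each library), with n = 4 libraries per genotype. Log2 fold changes are given ± their standard error.

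Xbp1 (ENSMUSG00000020484, GRCm38 chromosome 11, 5520659 to 5525893) was read first, since it is the targeted gene. It stood at 177, 163, 154 and 159 TPM in the wild-type libraries, at 144, 125, 157 and 124 TPM in Xbp1 SC-KO, at 282, 275, 249 and 268 TPM in S63del, and at 266, 253, 236 and 302 TPM in S63del/Xbp1 SC-KO. Xbp1 rose in S63del against wild type by 0.72 ± 0.06 on the log2 scale (limma adjusted p = 0.00023). The difference was -0.25 ± 0.09 between Xbp1 SC-KO and wild type (adjusted p = 0.999) and -0.03 ± 0.08 between S63del/Xbp1 SC-KO and S63del (adjusted p = 0.835). These values pool every exon and every cell type of the nerve, so they do not show the deleted part of the gene and do not check the knockout labels. Mpz (ENSMUSG00000056569, chromosome 1, 171150711 to 171161130) was the most abundant transcript in all 16 libraries, at 86807 ± 8015 TPM in wild type, 91032 ± 10740 TPM in Xbp1 SC-KO, 103523 ± 13051 TPM in S63del and 86802 ± 8540 TPM in S63del/Xbp1 SC-KO. No comparison called Mpz (adjusted p from 0.562 to 0.999).

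The comparison of S63del with wild type asks how nerves with the mutant myelin protein differ from those without it. Strain background may differ between these groups as well, and these libraries cannot tell the 2 apart. Genes of ER protein folding and disposal were higher in S63del. Of 21 measured ER chaperones and foldases, 17 rose and 0 fell (19 and 0 when adjusted over the list alone), with a mean log2 change of 0.84 and an adjusted p = 4.7e-11 in the test of the list against other genes (camera with its preset correlation). That call was lost with adjusted p = 0.224 with an estimated correlation. Hspa5 (ENSMUSG00000026864, BiP, the main ER chaperone) went from 319 ± 23.0 to 1012 ± 242 TPM, Hyou1 from 40.1 ± 1.62 to 106 ± 17.1 TPM, Dnajb9 from 66.0 ± 7.08 to 130.5 ± 11.3 TPM and Creld2 from 83.4 ± 3.38 to 262 ± 67.9 TPM. Of 18 genes of ER-associated degradation 11 rose and 0 fell (14 and 0 adjusted over the list alone, mean 0.56, adjusted p = 9.9e-06, and adjusted p = 0.133 with an estimated correlation). Under median-ratio scaling 6 rose (mean 0.47). Derl3 (ENSMUSG00000009092, chromosome 10, 75893413 to 75895941), a channel component for proteins leaving the ER, rose from 0.664 ± 0.143 to 32.6 ± 12.9 TPM, the largest log2 change of a named gene here at 4.25 ± 0.27 (adjusted p = 8.1e-05). Herpud1 and Syvn1, from the same pathway, rose by 0.72 ± 0.08 and 0.99 ± 0.13. Of 30 genes of ER translocation and ER-to-Golgi transport 12 rose, among them Wfs1 and Spcs2, and 1 fell (18 and 1 adjusted over the list alone, mean 0.21, adjusted p = 0.00014, and adjusted p = 0.413 with an estimated correlation), and under that scaling 10 rose and 1 fell (mean 0.12).

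The branch of the stress response that runs through PERK, ATF4 and CHOP was higher in part. Of 23 of its target genes 8 rose and 1 fell (8 and 1 adjusted over the list alone), including Ddit3, which encodes CHOP (37.3 ± 3.26 to 75.4 ± 15.1 TPM), and Ppp1r15a (74.5 ± 6.08 to 115 ± 5.19 TPM). The list as a whole was not called (mean 0.36, adjusted p = 0.081), but it passed without wild-type replicate 1 (adjusted p = 0.025) or replicate 4 (adjusted p = 0.043), and with fry (adjusted p = 0.019). Of 31 genes of amino acid synthesis, import and tRNA charging 13 rose and 1 fell (20 and 2 adjusted over the list alone, mean 0.25, adjusted p = 0.0015, and adjusted p = 0.220 with an estimated correlation), and under scaling 7 rose and 2 fell (mean 0.16). Slc1a4, an amino acid transporter, went from 11.1 ± 1.66 to 21.2 ± 1.43 TPM. Cytosolic heat shock genes rose as well, 9 of 12 with 0 falling (9 and 0 adjusted over the list alone, mean 0.77, adjusted p = 1.1e-05, and adjusted p = 0.220 with an estimated correlation), with Hspa1b at 19.7 ± 7.48 and 107 ± 13.3 TPM. Of 9 genes whose mRNA is known to be degraded by IRE1, 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.160), and the list's median was positive while its mean and test were negative. Among those, Col6a1 fell from 399.8 ± 24.6 to 241 ± 12.3 TPM.

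Lipid synthesis genes were lower in S63del. Of 24 cholesterol synthesis genes 21 fell and 0 rose (23 and 0 adjusted over the list alone), by a mean of -0.86 (adjusted p = 9.0e-21, and adjusted p = 0.219 with an estimated correlation). Dhcr24, the enzyme of a last step of the pathway, went from 839 ± 72.8 to 323 ± 58.4 TPM, and Acat2 from 177 ± 26.1 to 70.1 ± 10.8 TPM. Of 16 fatty acid synthesis genes 9 fell and 0 rose (13 and 0 adjusted over the list alone, mean -0.71, adjusted p = 4.2e-10, and adjusted p = 0.133 with an estimated correlation), with Fads1 at 512 ± 63.1 and 277 ± 9.03 TPM. Myelin genes went both ways: of 28, 10 fell and 6 rose (12 and 7 adjusted over the list alone, mean -0.07, adjusted p = 0.028, and adjusted p = 0.515 with an estimated correlation). That call also ended under median-ratio scaling (mean -0.16, adjusted p = 0.055), without wild-type replicate 3 (0.059) and without S63del replicate 2 (0.055). Ugt8a, which makes the myelin lipid galactosylceramide, fell from 1728 ± 84.8 to 975 ± 53.8 TPM and Mal from 4272 ± 270 to 2219 ± 188 TPM. Gjb1, the gap junction protein of Schwann cells, rose from 289 ± 4.45 to 471 ± 43.2 TPM.

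Genes of immature and repair Schwann cells rose: 15 of 23, with 2 falling (16 and 2 adjusted over the list alone, mean 0.91, adjusted p = 3.6e-07, and adjusted p = 0.133 with an estimated correlation). Pou3f1, a transcription factor of promyelinating Schwann cells, went from 34.5 ± 2.59 to 97.6 ± 14.1 TPM. Ednrb went from 33.3 ± 4.08 to 94.5 ± 13.9 TPM. Of 12 immediate early genes 4 rose and 0 fell (5 and 0 adjusted over the list alone, mean 0.62, adjusted p = 0.044, and adjusted p = 0.532 with an estimated correlation), a call that ended without wild-type replicate 2 (0.082) or 3 (0.117) or S63del replicate 1 (0.051) or 4 (0.076). Fibroblast and matrix genes fell, 10 of 20 with 2 rising (13 and 2 adjusted over the list alone, mean -0.36, adjusted p = 5.0e-08, and adjusted p = 0.133 with an estimated correlation), with Col3a1 at 1753 ± 199 and 923 ± 110 TPM. Of 22 macrophage genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, mean -0.30, adjusted p = 0.00019, and adjusted p = 0.515 with an estimated correlation, and 0.358 with fry). The riser was Lgals3, from 28.0 ± 3.59 to 132 ± 17.9 TPM, a galectin also made by other cell types, and Mrc1 fell from 20.7 ± 6.41 to 9.10 ± 1.91 TPM. Of 21 chemokine and interferon genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.729).

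Markers of muscle and fat were lower as lists in S63del, at a mean of -1.63 (adjusted p = 0.0059) and -0.54 (adjusted p = 0.015), although 0 of 14 and 0 of 12 members passed alone (0 in each adjusted over the list alone). Both calls were lost with adjusted p = 0.617 with an estimated correlation. The muscle call ended without wild-type replicate 1 (mean -0.24, adjusted p = 0.117) and under scaling (0.056), and the fat call ended without wild-type replicate 4 (-0.22, 0.108), without S63del replicate 1 (-0.18, 0.188) and under scaling (0.062). No call was made for Remak cells (2 of 9 rose, 1 fell; adjusted p = 0.916; mean and median positive, test negative), mitosis (0 of 24; 0.238), mitochondrially encoded mRNAs (0 of 13; 0.163), lymphocytes, mast cells and neutrophils (1 of 9 fell; 0.885), perineurial cells (0 of 10; 0.25), endothelial cells (1 of 14 fell; 0.195) or red blood cells (0 of 5; 0.885). Adjusted over the list alone these counts were the same. Single libraries turned some of these. Mitosis passed without S63del replicate 3 (0.030), and mitochondrial mRNAs without wild-type replicate 4 (0.012) or S63del replicate 2 (0.046). Perineurial cells passed without wild-type replicate 1 (0.013), and endothelial cells without wild-type replicate 2 (0.045) or 3 (0.023).

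The 10 named genes that rose most in S63del were Derl3, Cxcl10, Arc, Mir7061, Vtcn1, Sdf2l1, Gfap, Ppp2r2c, Crlf1 and Piwil4. Cxcl10, an interferon-induced chemokine, went from 3.15 ± 1.26 to 45.7 ± 19.4 TPM. Gfap, an intermediate filament of immature and Remak Schwann cells, went from 4.60 ± 1.71 to 38.2 ± 6.16 TPM, and Sdf2l1, an ER chaperone cofactor, from 18.3 ± 5.43 to 141 ± 55.7 TPM. The call of Mir7061 ended under 10 of 16 alternatives (adjusted p from 0.066 to 0.092), 6 of them the removal of wild-type replicate 1 or 3 or any S63del library. The full set was 19 alternatives, and Mir7061 was not tested in the rest. By name Mir7061 is a small RNA, while the libraries were selected for polyadenylated RNA. The 10 that fell most were Calcoco2, Aldoc, Pcsk6, Scg5, Npy6r, Tuba8, Igf2, Cnmd, Crybb1 and Folh1. Aldoc, a glycolytic enzyme, went from 28.1 ± 1.71 to 2.66 ± 0.637 TPM. Pcsk6, a proprotein convertase, went from 53.4 ± 4.61 to 9.07 ± 2.57 TPM, and Igf2, a growth factor, from 156 ± 55.1 to 32.0 ± 5.17 TPM.

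In limma, 3390 of 17215 genes tested passed in this comparison, 2385 higher and 1005 lower in S63del. The split depended on the scaling: median-ratio scaling gave 1495 higher and 1461 lower, edgeR on recovered reads gave 1709 and 1615, and the authors' deposited table gave 1828 and 1947. No called list and no named gene above turned its sign under that scaling, while the mean of the Remak list, which was not called, went from 0.08 to -2.7e-05. In simulated data with the spread of this comparison, 45% of 1.5-fold and 80% of 2-fold changes were recovered.

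**Figure D1:**
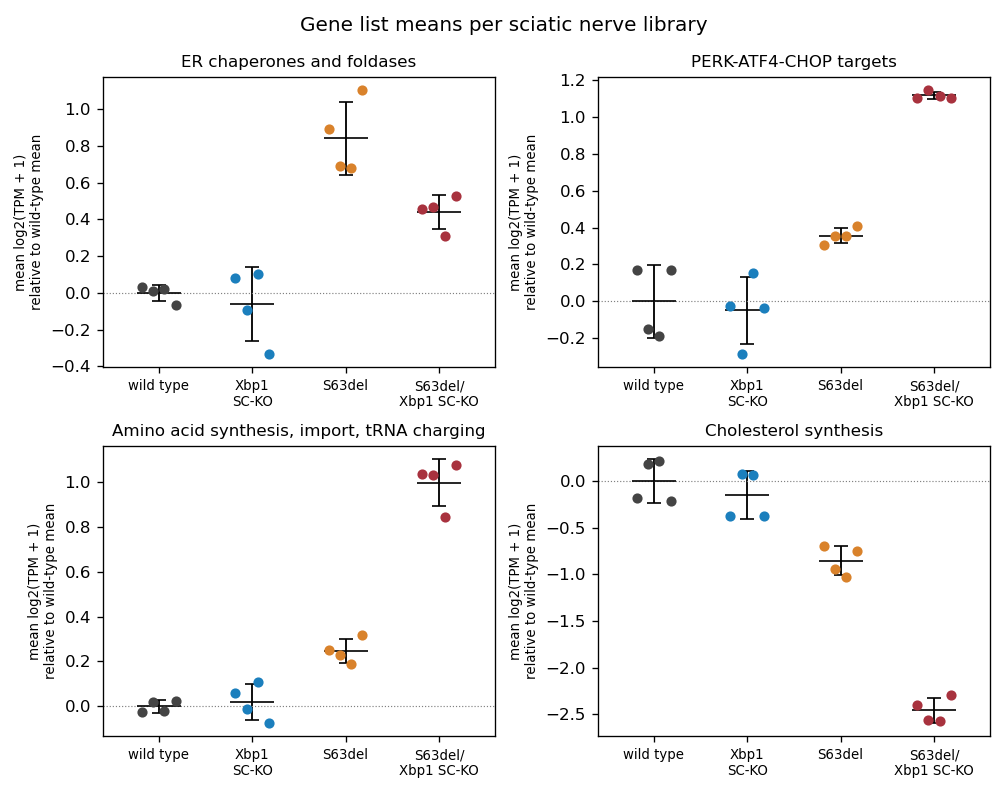
Mean log2(TPM + 1) of 4 gene lists in each library, relative to the mean of the wild-type libraries, with points for libraries (n = 4 per genotype), long bars for means and whiskers for SD. ER chaperones stood at 0.84 in S63del and 0.44 in S63del/Xbp1 SC-KO, PERK-ATF4-CHOP targets at 0.36 and 1.12, amino acid genes at 0.25 and 0.99, and cholesterol genes at -0.85 and -2.46.

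By an exact permutation test of the libraries, two-sided, each of these 4 list means differed between S63del and wild type and between S63del/Xbp1 SC-KO and S63del at p = 0.0286, the smallest that the 70 arrangements allow.

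The comparison of Xbp1 SC-KO with wild type asks what loss of Xbp1 changes in a nerve without the mutant protein. In limma, 6 of 17154 genes passed, 3 higher (Snord11, Gm22940 and Mir6912) and 3 lower (Rpl3-ps1, Gm9770 and Gm6166). At an unadjusted p under 0.05 there were 555, fewer than that threshold passes on average when no gene changes. Only Rpl3-ps1 met the rule for named genes, and the other 5 were named after their values were seen. Rpl3-ps1 (ENSMUSG00000084349, chromosome X, 13202571 to 13203780), a processed pseudogene of a ribosomal protein gene, fell from 104 ± 5.75 to 41.7 ± 3.08 TPM (log2 change -1.29 ± 0.07, adjusted p = 0.00068). The authors' deposited table called 10 genes, with Krt5 (log2 change 2.15) and Krt17 (1.84), keratins of basal epithelium, and the pseudogenes Rps19-ps6 and Tmem181b-ps higher, and Lgals2 (-2.10), Rpl3-ps1, Gm6166, Gm9770, Gm10093 and Gm5898 lower. With edgeR on the recovered reads 2 passed, Rpl3-ps1 and Gm6166. None of the 3 genes higher in limma was called by edgeR or by the authors. By name, Snord11 and Mir6912 are small RNAs, while the libraries were selected for polyadenylated RNA.

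No member of any list passed over all genes in Xbp1 SC-KO, and adjusted over the list alone only the 5 red blood cell genes did. Derl3 stood at 0.664 ± 0.143 TPM in wild type and 1.45 ± 0.378 TPM in Xbp1 SC-KO (adjusted p = 0.999), and Dnajb9 at 66.0 ± 7.08 and 54.1 ± 11.1 TPM (adjusted p = 0.999). With the preset correlation camera called 9 lists: red blood cells higher (mean 1.88, adjusted p = 6.9e-07) and endothelial cells higher (0.18, 0.014), and lower cholesterol synthesis (-0.15, 9.1e-05), mitochondrial mRNAs (-0.15, 0.0020), ER translocation (-0.06, 0.0041), fatty acid synthesis (-0.14, 0.011), Remak cells (-0.12, 0.018), ER chaperones (-0.06, 0.023) and perineurial cells (-0.23, 0.044). For each of the 9 the call was lost, with adjusted p = 0.774 with an estimated correlation, and with fry (0.916). Leaving out single libraries also ended each of these calls except that of red blood cells, as for cholesterol synthesis without Xbp1 SC-KO replicate 1 (-0.08, 0.199), endothelial cells without wild-type replicate 3 (0.09, 0.280) and perineurial cells without Xbp1 SC-KO replicate 4 (0.01, 0.652). The 15 other lists were not called with all 8 libraries (adjusted p from 0.058 to 0.937), and in ER-associated degradation, the amino acid list and the lymphocyte list the signs of mean, median and test differed. Some of the 15 passed when 1 library was left out. Chemokines and interferon passed without wild-type replicate 1 (0.14, 0.032) or 3 (0.15, 0.011) or Xbp1 SC-KO replicate 4 (0.21, 0.0023), and under scaling (0.09, 0.042). Mitosis passed without wild-type replicate 1 (0.17, 0.039) or 3 (0.17, 0.034) or Xbp1 SC-KO replicate 4 (0.20, 0.014). Heat shock passed without wild-type replicate 1 (0.16, 0.039) or Xbp1 SC-KO replicate 4 (0.14, 0.043), immediate early genes without wild-type replicate 4 (0.21, 0.031) and myelin without Xbp1 SC-KO replicate 3 (0.09, 0.0035). Fibroblasts passed without wild-type replicate 1 (-0.15, 0.045) or 4 (-0.12, 0.048) or Xbp1 SC-KO replicate 1 (-0.26, 0.0025) or 3 (-0.21, 0.0047), and adipocytes without wild-type replicate 3 (-0.38, 0.0055) or Xbp1 SC-KO replicate 3 (-0.31, 0.047). Macrophages passed without wild-type replicate 4 (-0.13, 0.040) or Xbp1 SC-KO replicate 1 (-0.22, 0.017), and skeletal muscle without wild-type replicate 3 (-1.18, 0.039) or 4 (-1.45, 0.0035). Without both wild-type replicate 1 and Xbp1 SC-KO replicate 4, mitosis (0.26, 0.0011), heat shock (0.23, 0.00073), chemokines (0.25, 0.00024), macrophages (0.30, 6.2e-06) and skeletal muscle (-0.66, 9.5e-06) passed. Xbp1 SC-KO replicate 4 was high in muscle transcripts (list mean 2.99 against wild type). Without it the ER chaperone list stood at 0.03 and the macrophage list moved from -0.05 to 0.19 (adjusted p = 0.014), while skeletal muscle moved from -0.74 to -2.08 (adjusted p = 3.5e-07).

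Every library moved this small count by more than 1.5 times. It was 1 without wild-type replicate 1, 3 or 4 or Xbp1 SC-KO replicate 3 or 4, 2 without wild-type replicate 2, and 3 without Xbp1 SC-KO replicate 1 or 2. In simulated data with the spread of this comparison, limma recovered 40% of 1.5-fold and 70% of 2-fold changes. In simulated reads, edgeR recovered 16% and 61%.

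The comparison of S63del/Xbp1 SC-KO with S63del asks what loss of Xbp1 changes when the mutant protein is present. Here too strain background may differ between the groups. Cholesterol synthesis genes fell together: 24 of 24 tested (24 adjusted over the list alone), by a mean of -1.67 (adjusted p = 2.8e-29, and adjusted p = 0.095 with an estimated correlation). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), an early enzyme of the pathway, went from 1467 ± 216 to 281 ± 52.0 TPM, where wild type stood at 2999 ± 427 TPM. Sc5d, Sqle, Msmo1 and Hsd17b7 fell by 2.10, 1.81, 1.86 and 2.07 on the log2 scale. Relative to wild type, the list stood at -0.85 ± 0.16 in S63del and -2.46 ± 0.14 in S63del/Xbp1 SC-KO. Of 16 fatty acid synthesis genes 6 fell and 0 rose (6 and 0 adjusted over the list alone, mean -0.67, adjusted p = 7.8e-06, and adjusted p = 0.296 with an estimated correlation), with Fads2 at 197 ± 34.7 and 60.1 ± 8.29 TPM. The adipocyte list, whose cells also make lipid, stood at -0.57 (adjusted p = 0.029, and adjusted p = 0.677 with an estimated correlation), with 0 of 12 members past the test over all genes or adjusted over the list alone. That call ended under scaling (0.068), without S63del replicate 2 (-0.44, 0.056) or 4 (-0.38, 0.123) and without S63del/Xbp1 SC-KO replicate 2 (-0.30, 0.182) or 3 (-0.51, 0.060).

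Genes downstream of PERK and ATF4 rose further. Of 22 PERK-ATF4-CHOP targets 14 rose and 3 fell (14 and 3 adjusted over the list alone, mean 0.81, adjusted p = 1.7e-05, and adjusted p = 0.057 with an estimated correlation). Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), a pseudokinase induced by CHOP, went from 12.1 ± 5.04 to 153 ± 9.86 TPM, Chac1, a glutathione-degrading enzyme, from 7.11 ± 2.14 to 62.3 ± 10.8 TPM. Sesn2 went from 9.76 ± 1.09 to 36.5 ± 4.40 TPM and Atf5 from 178 ± 13.2 to 362.5 ± 19.4 TPM. Of 31 amino acid synthesis, import and tRNA charging genes 25 rose and 0 fell (26 and 1 adjusted over the list alone, mean 0.75, adjusted p = 2.4e-13, and adjusted p = 0.143 with an estimated correlation). Asns, asparagine synthetase, went from 25.3 ± 3.04 to 100.1 ± 14.4 TPM, and Mthfd2, of mitochondrial folate metabolism, from 13.4 ± 4.26 to 108 ± 10.8 TPM. Relative to wild type, the amino acid list stood at 0.25 ± 0.05 in S63del and 0.99 ± 0.10 in S63del/Xbp1 SC-KO.

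Of 21 ER chaperones and foldases 11 fell and 0 rose (14 and 0 adjusted over the list alone, mean -0.40, adjusted p = 1.5e-07, and adjusted p = 0.407 with an estimated correlation). Dnajb9 went from 130.5 ± 11.3 to 61.9 ± 2.16 TPM, Hspa13 from 51.4 ± 3.51 to 26.1 ± 2.77 TPM and Dnajc3 from 147 ± 23.2 to 73.6 ± 2.08 TPM. Of 18 ER-associated degradation genes 7 fell and 1 rose (10 and 1 adjusted over the list alone, mean -0.26, adjusted p = 0.00093, and adjusted p = 0.296 with an estimated correlation). Derl3 fell from 32.6 ± 12.9 to 6.16 ± 1.46 TPM, and the riser was Ube2g2, a ubiquitin-conjugating enzyme, from 81.2 ± 9.88 to 119 ± 7.38 TPM. Of 30 ER translocation and ER-to-Golgi genes 17 fell and 3 rose (18 and 4 adjusted over the list alone, mean -0.22, adjusted p = 1.6e-06, and adjusted p = 0.334 with an estimated correlation), with Sec23b at 41.7 ± 1.55 and 27.7 ± 2.50 TPM, and under scaling 17 fell and 0 rose. Of 9 known IRE1 decay substrates 4 fell and 0 rose (7 and 0 adjusted over the list alone, mean -0.31, adjusted p = 0.00014, and adjusted p = 0.095 with an estimated correlation), among them Pdgfrb (97.3 ± 3.42 to 71.1 ± 3.30 TPM) and Bloc1s1 (76.6 ± 8.37 to 53.6 ± 2.91 TPM). Cytosolic heat shock genes fell in 4 of 12 cases, with 0 rising (4 and 0 adjusted over the list alone, mean -0.68, adjusted p = 4.0e-05, and adjusted p = 0.143 with an estimated correlation), and Hspa1a went from 41.9 ± 5.23 to 8.65 ± 1.48 TPM.

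Among myelin genes 10 of 28 fell and 4 rose (10 and 4 adjusted over the list alone, mean -0.20, adjusted p = 0.0069, and adjusted p = 0.604 with an estimated correlation). Ugt8a went from 975 ± 53.8 to 417 ± 68.8 TPM and Drp2, of the Schwann cell dystroglycan complex, from 715.5 ± 89.3 to 382 ± 47.6 TPM, while Nab2, a partner of the myelin regulator Egr2, rose from 71.0 ± 6.77 to 104 ± 7.86 TPM. Immature and repair Schwann cell genes went both ways, 5 of 23 up and 4 down (7 and 5 adjusted over the list alone, adjusted p = 0.913). Pou3f1 rose from 97.6 ± 14.1 to 394 ± 39.0 TPM and Tnc, a matrix protein, from 10.6 ± 3.80 to 30.4 ± 4.02 TPM, while Gfap fell from 38.2 ± 6.16 to 17.0 ± 3.03 TPM. Mitosis genes rose as a list (3 of 25 over all genes, 0 adjusted over the list alone, mean 0.49, adjusted p = 0.0023, and adjusted p = 0.657 with an estimated correlation, and 0.089 with fry).

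Of 10 lymphocyte, mast cell and neutrophil genes 5 fell and 1 rose (5 and 1 adjusted over the list alone, mean -0.67, adjusted p = 0.031, and adjusted p = 0.465 with an estimated correlation). That call ended under scaling (0.069), with fry (0.207), without S63del replicate 1 (-0.57, 0.107) and without S63del/Xbp1 SC-KO replicate 2 (-0.57, 0.083). The mast cell protease Mcpt4 went from 69.1 ± 15.1 to 23.6 ± 14.6 TPM (a call that ended with Xist as a covariate, at 0.056) and the stem cell factor receptor Kit from 2.67 ± 0.102 to 5.89 ± 0.947 TPM. Of 20 fibroblast and matrix genes 3 fell and 0 rose (2 and 0 adjusted over the list alone, mean -0.18, adjusted p = 0.031, and adjusted p = 0.639 with an estimated correlation), a call that ended with fry (0.207), without S63del replicate 2 (-0.14, 0.053) or 4 (-0.17, 0.084) and without S63del/Xbp1 SC-KO replicate 3 (-0.15, 0.097) or 4 (-0.13, 0.071). Lox, which cross-links collagen, fell from 356 ± 23.2 to 120.5 ± 24.5 TPM. No call was made for Remak cells (2 of 9 rose, 5 fell; adjusted p = 0.124), immediate early genes (4 of 12 rose; 0.617), macrophages (1 of 22 fell; 0.579; median positive, mean and test negative), chemokines and interferon (2 of 20 rose, 1 fell; 0.944), perineurial cells (1 of 10 fell; 0.052), mitochondrial mRNAs (0 of 13; 0.154), endothelial cells (0 of 14; 0.680), skeletal muscle (0 of 12; 0.913), red blood cells (0 of 5; 0.305) or sex-linked transcripts (0 of 5; 0.627). Skeletal muscle stood at 0.57, and at -0.58 without S63del/Xbp1 SC-KO replicate 4 (adjusted p = 0.032). Perineurial cells passed without S63del replicate 2 (0.037) or S63del/Xbp1 SC-KO replicate 3 (0.00042), mitochondrial mRNAs without S63del/Xbp1 SC-KO replicate 1 (0.00056), and immediate early genes with fry (0.036). Adjusted over the list alone, 1 immediate early gene fell as well and 0 macrophage genes passed, and the other counts were the same.

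The 10 named genes that rose most were Chil3, Trib3, Ear-ps2, Ear2, Cxcl14, Chac1, Mthfd2, Ina, Mir7664 and Igfbp2. Cxcl14, a chemokine that stood at 8.42 ± 1.86 TPM in wild type, went from 56.9 ± 12.9 to 473 ± 74.2 TPM. Chil3 went from 0.221 ± 0.0655 to 105 ± 43.5 TPM, but it also stood near 0 in wild-type replicate 4, at 0.125 TPM, against 78.7 to 96.5 TPM in the other wild-type libraries. Ear-ps2 was listed at 0 in every S63del library. The call of Mir7664 ended under 9 of 16 alternatives (adjusted p from 0.054 to 0.099), 4 of them the removal of S63del replicate 3 or 4 or S63del/Xbp1 SC-KO replicate 3 or 4. The full set was 19 alternatives, and Mir7664, by name also a small RNA, was not tested in the rest. The 10 that fell most were Jakmip2, Serpind1, Slc2a6, Them5, Cldn14, Hmgcs1, Ly9, Hspa1b, Ankfn1 and Cnmd. Serpind1, which encodes heparin cofactor II, went from 139 ± 13.2 to 18.1 ± 5.59 TPM, and Jakmip2, which binds microtubules, from 14.7 ± 3.06 to 0.964 ± 0.349 TPM.

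In limma, 4407 of 17355 genes tested passed, 2898 higher and 1509 lower in S63del/Xbp1 SC-KO. Median-ratio scaling gave 2356 higher and 2007 lower, edgeR on recovered reads 2505 and 2246, and the authors' deposited table gave 2582 and 2460. In simulated data with the spread of this comparison, 50% of 1.5-fold and 72% of 2-fold changes were recovered.

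**Figure D2:**
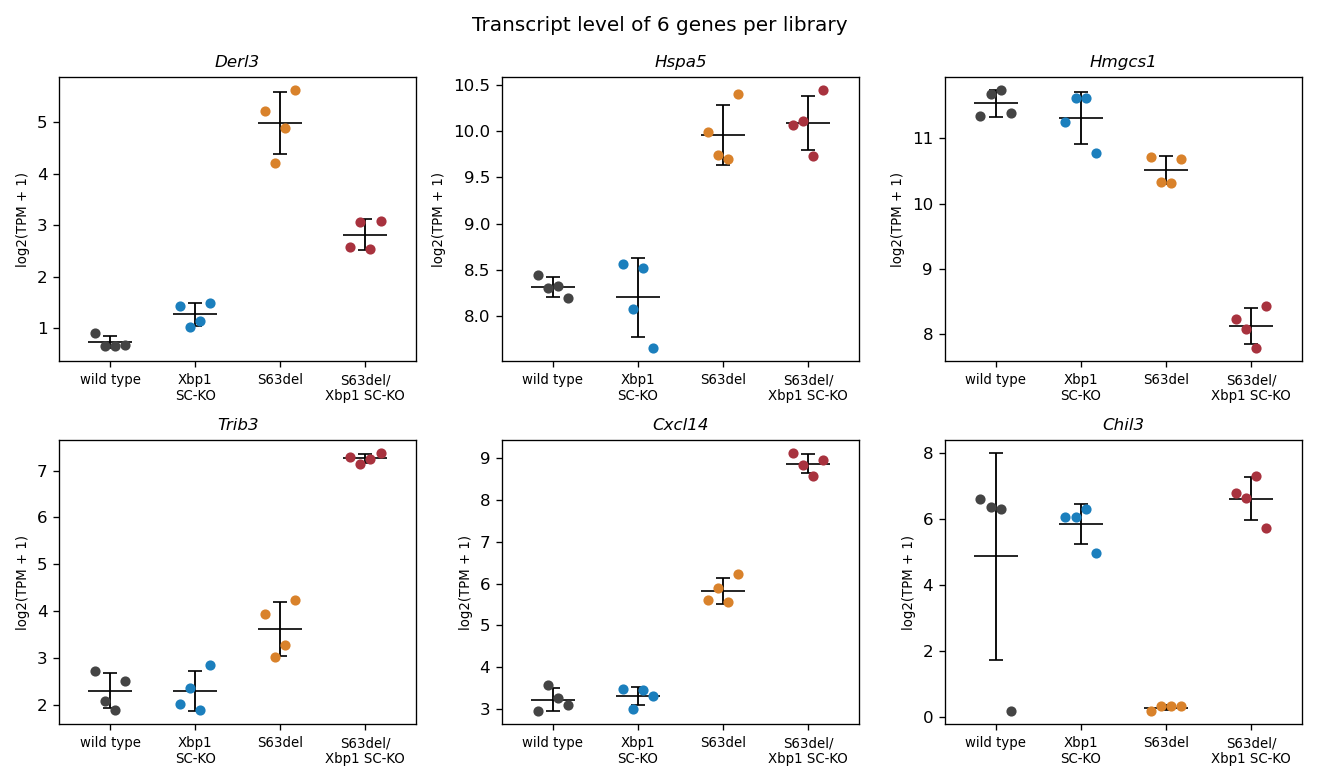
Level of 6 genes as log2(TPM + 1) in each library, by genotype, with points for libraries (n = 4 per genotype), long bars for means and whiskers for SD. Derl3 fell and Hspa5 stood at 1101 ± 221 TPM in S63del/Xbp1 SC-KO, Hmgcs1 stepped down, Trib3 and Cxcl14 stepped up, and Chil3 was near 0 in S63del and in 1 wild-type library.

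The interaction asks whether loss of Xbp1 acts differently with and without the S63del allele, as the effect in S63del minus the effect in Mpz wild type. The smallest adjusted p belonged to the cholesterol synthesis, amino acid and PERK-ATF4-CHOP lists. Of 25 cholesterol synthesis genes 21 were lower and 0 higher in the interaction (24 and 0 adjusted over the list alone, mean -1.46, adjusted p = 5.6e-32, and adjusted p = 0.055 with an estimated correlation), with Fdft1 at -1.71 ± 0.18. Of 31 amino acid genes 21 were higher (24 adjusted over the list alone, mean 0.73, adjusted p = 4.0e-19), and this was the only list of any comparison whose call held, at adjusted p = 0.036 with an estimated correlation. Of 23 PERK-ATF4-CHOP targets 11 were higher (12 adjusted over the list alone, mean 0.81, adjusted p = 1.7e-07, and adjusted p = 0.055 with an estimated correlation), including Ddit3 at 1.72 ± 0.17.

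ER chaperones (4 of 21 lower, 8 adjusted over the list alone, mean -0.34, adjusted p = 1.2e-05, and adjusted p = 0.390 with an estimated correlation, and 0.115 with fry) and ER-associated degradation (4 of 18 lower, 4 lower and 1 higher adjusted over the list alone, mean -0.27, adjusted p = 0.0020, and adjusted p = 0.323 with an estimated correlation) differed in the same direction as in the comparison within S63del, with Derl3 at -2.71 ± 0.34. So did heat shock genes (4 of 12 lower, 4 adjusted over the list alone, mean -0.75, adjusted p = 5.2e-05, and adjusted p = 0.230 with an estimated correlation), with Hspa1b at -2.63 ± 0.37, and myelin genes (8 of 28 lower and 1 higher, 9 and 1 adjusted over the list alone, mean -0.25, adjusted p = 0.00050, and adjusted p = 0.390 with an estimated correlation), with Ugt8a at -1.14 ± 0.17. IRE1 decay substrates (2 of 9 lower, 4 adjusted over the list alone, -0.26, adjusted p = 0.0012, and adjusted p = 0.167 with an estimated correlation) and fatty acid genes (4 of 16 lower, 4 adjusted over the list alone, -0.53, adjusted p = 0.00012, and adjusted p = 0.352 with an estimated correlation, and 0.0504 with fry) were also called. ER translocation was called at a mean of -0.17 (adjusted p = 0.00024, and adjusted p = 0.390 with an estimated correlation, and 0.115 with fry), although 1 of 30 members was higher and 0 lower (0 and 0 adjusted over the list alone).

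Mitosis (mean 0.38, adjusted p = 0.046), mitochondrial mRNAs (0.50, 0.0055), lymphocytes, mast cells and neutrophils (-0.68, 0.027) and red blood cells (-2.58, 0.0064) were called with 0 members past the test over all genes or adjusted over the list alone. These were lost at adjusted p = 0.869, 0.579, 0.390 and 0.390 with an estimated correlation, in that order, and none passed with fry (0.351, 0.115, 0.157 and 0.125). The mitosis call ended without any 1 of 10 libraries (adjusted p from 0.055 to 0.299), and the lymphocyte call without wild-type replicate 3, Xbp1 SC-KO replicate 1 or 4, S63del replicate 1 or S63del/Xbp1 SC-KO replicate 2 (0.063 to 0.087). The 11 other lists were not called (adjusted p from 0.166 to 0.997), and in the immature, immediate early, macrophage, chemokine and perineurial lists the signs of mean, median and test differed. Single libraries turned 2 of them: fibroblasts passed without Xbp1 SC-KO replicate 4 (0.018), and adipocytes without wild-type replicate 4 (0.026), Xbp1 SC-KO replicate 2 (0.031), S63del replicate 1 (0.0066) or S63del/Xbp1 SC-KO replicate 4 (0.037).

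In limma, 1871 of 18965 genes passed in the interaction, 1249 higher and 622 lower. With edgeR on recovered reads the split was 1113 higher and 856 lower. By the rule for named genes the highest were Chil3, Trib3, Ear-ps2, Chac1 and Cxcl14, and the lowest Mir3079, Them5, Jakmip2, Serpind1 and Cldn14. The calls of Chil3 and Ear-ps2 ended without any 1 of 11 and 12 libraries (adjusted p from 0.050 to 0.064 and from 0.054 to 0.070). That of Mir3079, by name also a small RNA, ended with Xist as a covariate (0.055) and without the 3 muscle-rich libraries (0.089). In simulated data, 23% of 1.5-fold and 61% of 2-fold interactions were recovered.

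Across 16490 genes tested in both, the effects of Xbp1 loss with and without S63del had a Pearson r of 0.110 (jackknife standard error over libraries 0.0843) and a Spearman rho of 0.189. Without Xbp1 SC-KO replicate 4 r was 0.037. Genes are not independent replicates, so these carry no p. Of the calls in Xbp1 SC-KO against wild type, 1 gene was also called the same way within S63del, Rpl3-ps1. The effect of S63del and the effect of Xbp1 loss within S63del share the S63del libraries, which by itself gave r = -0.498 in simulated data with no effect. The measured r was 0.0842 over 16735 genes, and 0.254 when 2 S63del libraries served each comparison, so that no library was shared. It was 0.0095 without S63del replicate 4. Of genes higher in S63del, 1041 rose further with Xbp1 loss where 401 were expected if the calls were independent. Of genes lower in S63del, 344 fell further where 86.2 were expected. Independence leaves out that genes with a small spread are called more often in both. These counts and the next come from TPM without median-ratio scaling, where the median gene rose in both comparisons (log2 change 0.078 and 0.050). That shift adds to the genes that rose in both, and the counts were not repeated under scaling. Genes that went up and then down numbered 216 (215 expected), and those that went down and then up 59 (161 expected). Sharing the S63del libraries pushes the 2 effects in opposite directions, as the simulated r shows. By itself it would raise these opposite counts and lower the counts of genes that moved the same way. In the 100 simulated draws with no effect, at most 0 genes were called in both comparisons.

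**Figure D3:**
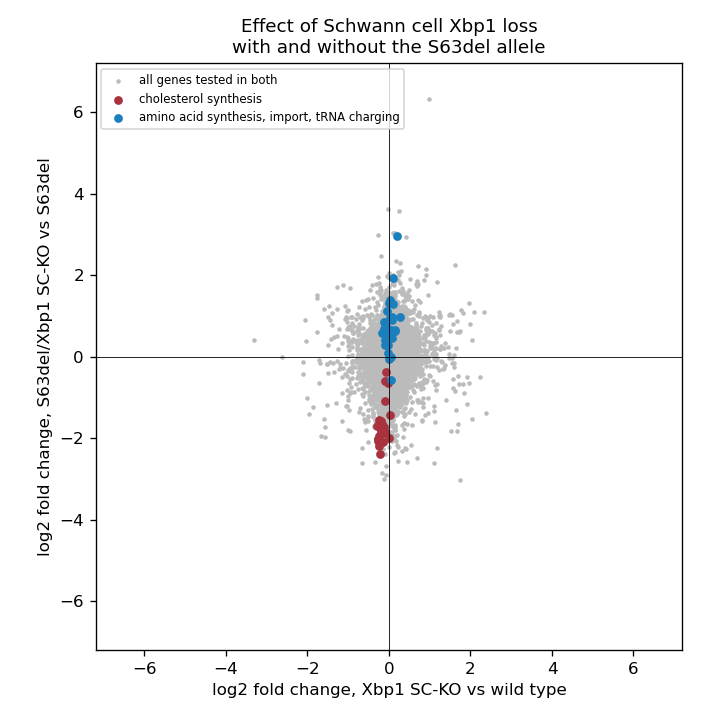
Log2 fold change of each gene after Xbp1 loss with the S63del allele (vertical axis) against that without it (horizontal axis), with grey points for the 16490 genes tested in both, red for cholesterol synthesis and blue for amino acid synthesis, import and tRNA charging. The 24 cholesterol genes tested within S63del lie below 0 on the vertical axis and near 0 on the horizontal axis, where their list mean was -0.15.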

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

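The tests of the cholesterol list against myelin and adipocyte genes, and the tests of the S63del allele, of macrophage number and of an inherited haplotype for Chil3 and the Ear genes, were chosen after the results were seen.

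Loss of Xbp1 acted differently with and without the S63del allele, by a test of the interaction, for 1871 genes. By log2 value, the lists called with the preset correlation were PERK-ATF4-CHOP targets (0.81), amino acid genes (0.73), mitochondrial mRNAs (0.50) and mitosis (0.38) on the higher side. On the lower side were red blood cells (-2.58), cholesterol synthesis (-1.46), heat shock (-0.75), lymphocytes with mast cells and neutrophils (-0.68), fatty acid synthesis (-0.53), ER chaperones (-0.34), ER-associated degradation (-0.27), IRE1 decay substrates (-0.26), myelin (-0.25) and ER translocation (-0.17). With an estimated correlation the amino acid list kept its call (adjusted p = 0.036) and the 13 others lost theirs (0.055 to 0.869). Mitochondrial mRNAs, mitosis, red blood cells and lymphocytes had 0 members called, and these and ER chaperones, ER translocation and fatty acid synthesis did not pass with fry (0.0504 to 0.351). The mitosis call also ended without any 1 of 10 libraries, and the lymphocyte call without any 1 of 5. Among named genes the interaction was 5.35 for Chil3, 3.65 for Trib3, 3.33 for Ear-ps2, 3.25 for Chac1, 2.95 for Cxcl14, -3.77 for Mir3079, -3.03 for Them5, -2.86 for Jakmip2, -2.83 for Serpind1 and -2.79 for Cldn14. The calls of Chil3 and Ear-ps2 were lost in 14 and 15 of 24 alternatives without a replicate block, of which 11 and 12 left out a single library, and that of Mir3079 in 2 of 22.

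Cholesterol synthesis genes were lower in S63del/Xbp1 SC-KO than in S63del in 24 of 24 cases, by a mean of -1.67. Unequal sexes were argued against, since the mean was -1.69 with Xist as a covariate. Less RNA from myelinating Schwann cells was argued against, since the list fell further than the myelin list by a log2 value of -1.47. Fewer adipocytes was first tested as the difference from the adipocyte list, which left it undecided because the groups overlapped (-1.11), and a covariate was then chosen, with which the mean was -1.67 and 24 genes were still called. Whether the rate of lipid synthesis differed in Schwann cells that lack Xbp1 was not tested.

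Only 6 genes changed in Xbp1 SC-KO against wild type by limma. Muscle transcripts in 2 libraries were tested as the reason, and 1 gene passed without wild-type replicate 1 and Xbp1 SC-KO replicate 4. That met the bound set in advance against this reason. Leaving out any single library also lowered the count, so the loss of libraries alone could give this outcome and the test does not decide. Too few replicates for changes of 2-fold was tested in simulated data, where limma recovered 70% and edgeR 61% of changes of that size. This too met its bound set in advance. The simulation drew noise for each gene independently and changed 100 genes 2-fold and 100 genes 1.5-fold together, which eases the adjusted threshold. In the data, limma did not call Krt5 (log2 change 1.67, adjusted p = 0.847), Krt17 (1.545, 0.538) or Lgals2 (-1.95, 0.065). The test thus does not decide for 2-fold changes, and smaller changes stay open as well. A candidate explanation is that the unstressed nerve makes little spliced XBP1, which was not tested.

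Chil3, Ear1, Ear2 and Ear-ps2, genes of certain macrophages and eosinophils, were near 0 or low in S63del and in wild-type replicate 4, and high elsewhere. Ear1 was added after its values were seen. For the S63del allele as the whole cause, 2 libraries that carry it stood above the median of those without it. The genes were picked as high in S63del/Xbp1 SC-KO, which carries the allele, so this outcome was fixed by the choice. It describes the pattern of these genes and is no separate test of the allele. Fewer macrophages overall was argued against, since the genes fell beyond the macrophage list by at least a log2 value of -3.54. Fewer of only those cells that express these genes was not tested. A single inherited haplotype near the genes was argued against, since they lie on 2 chromosomes. Another difference between animals or dissections may remain, and RNA from lung macrophages is treated among the other observations.

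The real grouping was set against other splits of the same libraries. For S63del against wild type, 1 of 35 splits, the real one, reached 3390 genes, and the highest other gave 5. For S63del/Xbp1 SC-KO against S63del, 1 of 35 reached 4407, and the highest other gave 13. In both, no other split came near the real count, and 1 of 35 is the smallest share these splits allow. The other splits mix the genotypes, which widens the spread within groups, so their counts do not show what chance alone would give. For Xbp1 SC-KO against wild type, 3 of 35 splits gave 6 genes or more, up to 20, so chance cannot be excluded. For the interaction, 3 of 100 drawn splits reached 1871, up to 2589 in another split. Both others kept the real S63del and S63del/Xbp1 SC-KO libraries apart, and the highest count without that was 24. The share thus follows from the difference between these groups, so these splits do not decide whether chance is excluded for the interaction.

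Single libraries stood far from the other 3 of their genotype in 16 of 211 groups tested, where chance marks about 1 in 20 groups, or 10.6 here. Of these, 6 were in wild-type replicate 4 and 3 in Xbp1 SC-KO replicate 4. As log2 list means relative to wild type, Xbp1 SC-KO replicate 4 stood at 2.99 for skeletal muscle, -1.14 for perineurial cells and -0.42 for Remak cells, wild-type replicate 4 at 0.067 for ER-associated degradation and -0.27 for chemokines and interferon, and S63del/Xbp1 SC-KO replicate 3 at 0.56 for endothelial cells. In TPM, wild-type replicate 4 stood at 1.27 for Cxcl10, 0.125 for Chil3, 0 for Ear-ps2 and 4.54 for Mir3079, wild-type replicate 1 at 0.877 for Derl3, wild-type replicate 2 at 3.42 for Arc, S63del replicate 1 at 0.123 for Chil3, S63del replicate 2 at 3.36 for Tuba8, and Xbp1 SC-KO replicate 2 at 122 for Them5. Xbp1 SC-KO replicate 3 had the most reads on listed genes, at 20.8 M against 16.7 to 17.2 M in the other 3 libraries.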

How the results depend on the processing

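The edgeR and DESeq2 fits on recovered reads and the removal of 3 muscle-rich libraries were chosen after the data were examined. For S63del against wild type the count was 2160 with a replicate block, where 3390 is the count without, and from 2312 to 3051 with a library left out. Replicate numbers paired poorly across genotypes: 2, 1 and 1 of 4 libraries per comparison were closest to the library of the same number. The block changed the call of 3 lists: chemokines and interferon in Xbp1 SC-KO against wild type (adjusted p = 0.043) and perineurial cells in S63del/Xbp1 SC-KO against S63del (0.025) passed with it, and mitosis in the interaction did not (0.067). For Xbp1 SC-KO against wild type (6 genes) the count was 1 with a pseudocount of 0.1, 1 with a replicate block, 1 with Xist as a covariate, 3 in the 16-sample fit, 10 in the authors' deposited table, 2 with edgeR, 10 with DESeq2, 1 without the muscle-rich libraries, and from 1 to 3 with a library left out. For S63del/Xbp1 SC-KO against S63del the counts ran from 3441 to 5042 and for the interaction from 1353 to 2344.

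ER chaperones in Xbp1 SC-KO against wild type (-0.06) stood at 0.041 without the muscle-rich libraries, and from -0.11 (without Xbp1 SC-KO replicate 3) to 0.03 (without replicate 4) with a library left out. Macrophages there (-0.05) stood at 0.30 and from -0.22 to 0.19. Skeletal muscle in S63del/Xbp1 SC-KO against S63del (0.57) stood at -0.58 and from -0.58 to 1.17. The mean turned its sign under at least 1 alternative in 4 of 24 lists in S63del against wild type, 13 in Xbp1 SC-KO against wild type, 3 in S63del/Xbp1 SC-KO against S63del and 8 in the interaction. Called lists among these were ER chaperones and perineurial cells in Xbp1 SC-KO against wild type, the latter at -0.23, and at 0.01 without Xbp1 SC-KO replicate 4. The correlation of the S63del effect with the effect of Xbp1 loss in S63del (0.0842) was 0.254 with no S63del library shared. Apart from the sharing of libraries, the cause was not tested.

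Of named genes called, 71 of 81 in S63del against wild type, 1 of 1 in Xbp1 SC-KO against wild type, 67 of 81 in S63del/Xbp1 SC-KO against S63del and 35 of 50 in the interaction kept direction and call under every alternative in which the gene was tested. Of lists called, 9 of 14, 0 of 9, 10 of 14 and 7 of 14 did in the same order under the alternatives run for lists, namely fry, the pseudocount, scaling, the block, single libraries left out and the muscle-rich libraries left out. The estimated correlation was not counted. With limma, changes of 1.5-fold were recovered in 23% (interaction) to 50% (S63del/Xbp1 SC-KO against S63del) of simulated cases. With edgeR, 16% of them were recovered in Xbp1 SC-KO against wild type. Smaller changes were thus not reliably detectable with these libraries.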

Other observations

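The genes in this part were chosen after their values were seen, as were the rate of calls near Xbp1, the gene definition of the haplotype test and the reading of the lung macrophage test as undecided.

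Rpl3-ps1 stood at 104 ± 5.75 TPM in wild type, 41.7 ± 3.08 in Xbp1 SC-KO, 105 ± 9.88 in S63del and 49.5 ± 19.1 in S63del/Xbp1 SC-KO. Lgals2 (chromosome 15, 78850860 to 78855529), a galectin, stood at 21.1 ± 2.59, 4.94 ± 1.94, 18.8 ± 1.55 and 6.76 ± 2.47 TPM in the same order. In limma Lgals2 changed by -1.95 in Xbp1 SC-KO (adjusted p = 0.065) and by -1.40 in S63del/Xbp1 SC-KO against S63del (adjusted p = 0.0013).

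Calcoco2 (chromosome 11, 96099326 to 96111964), a receptor of autophagy, and its neighbour Ttll6 (96133786 to 96165451) were both lower in S63del than in wild type. Calcoco2 stood at 13.9 ± 2.61 TPM in wild type and 0.790 ± 0.328 in S63del, and Ttll6 at 17.6 ± 4.27 and 5.71 ± 1.33. In S63del/Xbp1 SC-KO they stood at 0.0645 ± 0.0746 and 0.317 ± 0.144 TPM. Whether strain variants near these neighbours account for their levels was not tested. Ttll6 also fell between S63del and S63del/Xbp1 SC-KO, at -2.33 on the log2 scale (adjusted p = 9.6e-05), with -2.49 in the interaction (adjusted p = 0.00010).

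Krt17, a keratin, stood at 3.59 ± 1.48 TPM in wild type, 12.8 ± 5.82 in Xbp1 SC-KO, 10.4 ± 2.23 in S63del and 23.2 ± 10.5 in S63del/Xbp1 SC-KO. Atf4 stood at 274 ± 30.1 TPM in S63del and 537 ± 48.2 in S63del/Xbp1 SC-KO (log2 change 0.97, adjusted p = 0.00020). Ern1, which encodes IRE1, stood at 10.1 ± 0.690 and 12.2 ± 1.66 TPM there (adjusted p = 0.149).

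Strain variants linked to the floxed Xbp1 allele could bring calls near Xbp1, since the sample descriptions place the floxed and S63del alleles on different strains. Variants linked to S63del or to the Cre line were not tested in this way. Of the calls in Xbp1 SC-KO against wild type 0% lay within 20 Mb of Xbp1, which argues against linkage as the source of most of those 6. In S63del/Xbp1 SC-KO against S63del the 159 genes tested there could hold at most 3.61% of the calls, so a share of the calls, the test planned first, decided nothing. Of the 159 genes 38 (23.9%) were called, where 25.4% of 17196 tested genes elsewhere were (Fisher exact p = 0.715). The odds ratio was 0.922 (95% interval 0.622 to 1.34), so an excess was not seen and a small excess stays open.

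RNA or reads of lung (alveolar) macrophages in the other libraries might explain the low Chil3 and Ear genes of S63del and wild-type replicate 4. Of 7 further markers of those cells 0 were low in the same way, which met the bound set in advance against this explanation. It is left undecided because 4 markers stayed below 10 TPM in every library and 2 were never below 1 TPM, so 1 marker was informative, and 3 were lowest in wild-type replicate 4. Outside those markers, Plet1 followed the pattern, at 1.13 ± 0.802 TPM in S63del and 0.629 in wild-type replicate 4. It stood at 8.50 ± 5.41 TPM in S63del/Xbp1 SC-KO. F7, Mcemp1 and Ear10 averaged 0.0269, 0.241 and 0 TPM in S63del, and 1.64, 1.97 and 1.32 in S63del/Xbp1 SC-KO. Each had a wild-type library at 0.

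Segregating strain haplotypes might make genes low in some libraries and high in others across genotypes. Among 434 such genes, 18 of them protein-coding, 31 pairs shared a pattern and 1 pair lay within 20 Mb, where shuffled positions gave 0.73 on average (permutation p = 0.516). That is no more than chance, and the test is left undecided because few genes were protein-coding.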
